A study of Mus musculus with 80 samples.

How the data were processed

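RNA from the eyes of 40 C57BL/6 mice fed ad libitum was measured on nylon filter arrays, which carry spotted cDNA and are read by the radioactivity of labelled cDNA bound to each spot. Per the labels' protocols, tissue was broken up with glass beads, total RNA was taken with a column kit (RNeasy), and cDNA was made with reverse transcriptase in the presence of 33P-dCTP. Each mouse was hybridised to 2 array designs, called A and B here, which gave 80 arrays with 8448 probes each and 16896 probes in all. The mice are separate animals, so n counts mice.

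The deposited values are scores: each array had a mean of 0 and an SD near 1 (0.9998 to 1.0004 over the 80 arrays), with medians between -0.10 and 0 except for the design A array of mouse 59 (0.07), so the deposited score of a probe is its distance from the array's mean in units of that array's SD (z). That each array was standardised was read from the values. The brightness, the background and the base of any logarithm behind these scores are not given in the sources used here, so differences below are in z and are not folds. The plan written before the data were examined assumed log2 values and said that standardised values would be used as deposited, which was done. A further setting written into the plan, z-scores per array, would have repeated the deposited scale and was not run. No signal over background could be computed, and the number of arrays limits the precision. All columns of values were matched to a mouse by the labels.

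Groups were sex and age class, with 5 mice in each of 8 groups and classes of 17 to 44, 169 to 194, 476 to 499 and 704 to 743 days. The youngest class holds 5 mice of 17 to 21 days (2 males, 3 females) and 5 of 33 to 44 days (3 males, 2 females). Replicate numbers follow the running numbers in the labels, which fall into 5 sets of 8 mice with 1 mouse of each group per set. The labels do not say that a set was a batch. On design A, 70.8% of the first principal component's variance lay between sets and 14.0% between age classes, and on design B 72.0% and 6.18%. In all 5 sets the mice were numbered from the youngest to the oldest class, and the rank of a mouse within its set followed age with r = 0.967 over the 40 mice. An effect of processing order, if processing followed the running numbers, therefore cannot be told apart from age in this design.

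All tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes), fitted separately to each design over all 40 mice, with Benjamini-Hochberg adjustment over the probes of both designs and a threshold of 0.05. The age slope was the coefficient of age in years (365 days) beside sex. Contrasts of age classes and the sex difference came from a model of 4 age classes and sex, the contrast within the youngest class from a model that split that class, and the interaction from age, sex and their product. About 845 probes pass an unadjusted p of 0.05 by chance alone. Gene lists were tested with limma's camera at a preset correlation of 0.01 over 1 probe per gene, the one with the highest mean score, with adjustment over the lists. Of 27 lists of cell types, complexes and pathways fixed before the data were examined, 21 had at least 5 measured genes and were tested. List tests were planned for the age slope, old against adult, the youngest class and sex, and were added for adult against young and the interaction after the data had been seen.

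Probe names came from the platform annotation. Of the 16896 probes, 9663 name 1 gene, 436 name several and 6797 name none. Entrez IDs matched 9641 of the 9663 probes to the RefSeq gene table of GRCm38.p6, and no symbol had to be updated. The named probes cover 7151 genes, and no gene was taken from a probe that names several. The array design's genome build is not given in the sources used here, so no coordinates are printed.

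The genes named were fixed by a rule: the 6 largest rises and 6 largest falls past the threshold with 1 probe per gene (the one with the lowest p), or the 5 genes with the lowest p where fewer than 5 genes pass. Up to 4 members with the lowest p were added for each list described, and for sex every measured gene of the X- and Y-linked list. Which lists are described was chosen after the values were seen, as were Fabp5, Tap2, H2-K1, Rpl10, Rpl31, Rpl41, Mcm4, second probes of Ctsd, Sparc, Mdh1, Col1a2 and Uchl1, the entries of Hspb1 and Fth1 outside the rule, and unnamed probes. Where a gene with a call has several probes, the values or the signs of the others are given.

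The places of the probes on the filters were inferred from the values after the data had been seen: probes whose numbers differ by a fixed step (11 steps were compared) had like deviations, which gave 22 print series of 384 probes in 16 lines of 24 columns. With 24 columns, 38 probes that followed Crygb lay a median of 2.91 grid steps from it, against 6.08 with 16 columns. Local centring subtracted from each score the median deviation of the other probes within 2 grid steps on the same array.

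The other settings fixed before the data were examined were quantile normalization, removal of the dimmest 25% of probes, the set as a block, array weights, a variance trend with robust eBayes, the array median as a covariate, the mean of a gene's probes, log2 of age, an F test over classes, fits without the mice of 17 to 21 days or without the youngest class, fits on only the mice compared, an estimated correlation in camera, leaving out each mouse, and leaving out mouse 27, whose description names another mouse than its title. Chosen after seeing the data were fits without the design A array of mouse 59, on sets 1 to 3 or on sets 4 and 5 (the latter without that array), with local or print-series centring, without the Crygb print series, and with the rank within the set as a covariate, which also had the set as a block and left out that array. Falls of the Crygb print series within and beyond 5 grid steps were set apart after the data had been seen. Each model was first tested on simulated scores with 200 of 16896 probes changed: at 0.6 z it recovered 197 for the age slope (per year), 180 for old against adult, 167 for adult against young, 146 for the youngest class, 194 for sex and 171 for the interaction. At 0.3 z it recovered 175, 94, 67, 28, 143 and 88 in that order. The simulated scores were drawn independently for each probe and mouse, without set differences or likeness between neighbouring spots. These recoveries may therefore be higher than in the real data.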

Results

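The series compared the eyes of 40 C57BL/6 mice by age and sex, with 5 males and 5 females in each of 4 age classes (17 to 44, 169 to 194, 476 to 499 and 704 to 743 days). Each eye sample gave values for 16896 probes on 2 filter arrays, as scores in units of the array's SD (z). The median correlation of an array with the others of its design lay between 0.890 and 0.950 for 39 arrays of design A and between 0.894 and 0.952 for the 40 of design B, and the highest correlation of any pair was 0.981. The design A array of mouse 59 (male, 169 to 194 days, replicate 5) stood apart: its mean correlation with the others was 0.426, with r = 0.887 to their mean over the first probes and -0.0185 over the last 3168. It was kept, and values without it are given where they end a call or move a count by over 1.5 times.

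**Figure D1:**
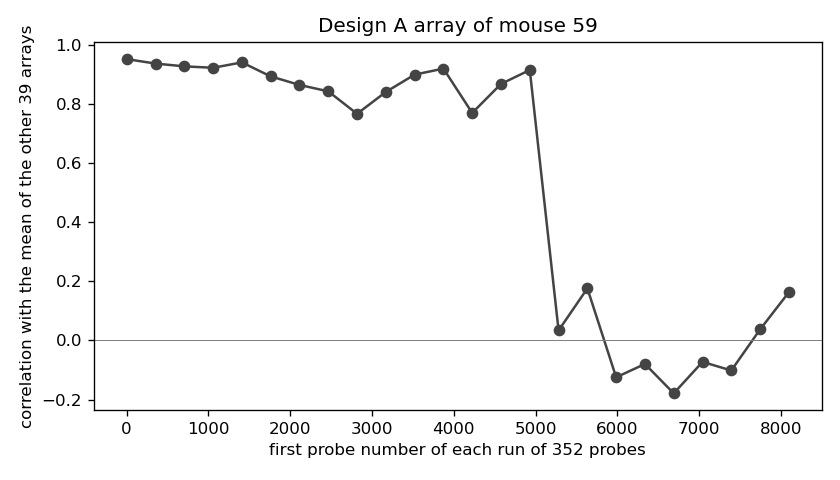
Pearson correlation of the design A array of mouse 59 with the mean of the other 39 design A arrays (y axis), for successive runs of probes in table order (x axis, probe number). The correlation was 0.887 over the probes before the drop and -0.0185 over the 3168 probes after it.

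The main question was which transcripts follow age over the whole span from 17 to 743 days. Crygb, which codes for the structural lens protein gamma-B crystallin, showed the largest fall of a named gene: it fell by 1.39 z per year (SE 0.148, n = 40 mice, adjusted p = 7.14e-08), from 3.46 ± 0.368 (SD, n = 10) in the youngest class through 1.27 ± 0.506 and 0.641 ± 0.0749 to 0.449 ± 0.152 in the oldest. The 1.27 ± 0.506 includes the -0.15 of mouse 59, from the last part of its design A array. Cryab, the alpha-B crystallin and small heat shock protein, fell by 0.349 z per year (SE 0.0516, adjusted p = 3.57e-05), and Fabp5, a fatty acid-binding protein, by 0.474 (SE 0.0694, adjusted p = 3.57e-05). Mrps25, a protein of the mitochondrial ribosome's small subunit, showed the largest named rise, 0.354 z per year (SE 0.0415, adjusted p = 7.63e-07), from -0.212 ± 0.204 in the youngest class to 0.458 ± 0.149 in the oldest. Ctsd, the lysosomal protease cathepsin D, rose on both of its probes (0.188 ± 0.0278 and 0.173 ± 0.0371 z per year, SE), and Fth1, the ferritin heavy chain that stores iron, rose by 0.215 ± 0.0514. On the inferred layout both Ctsd probes lay close together in the same grid line of print series 13 of design B. That series held 32 rises and 0 falls, so the pair is not independent. The second gave 0.0934 after local centring (adjusted p = 0.107). Of the list of further lens genes 2 were measured, Tmem40 and Gja1, a connexin that other eye tissues also express, and both had slopes above 0 (median 0.0267) and did not pass.

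**Figure D2:**
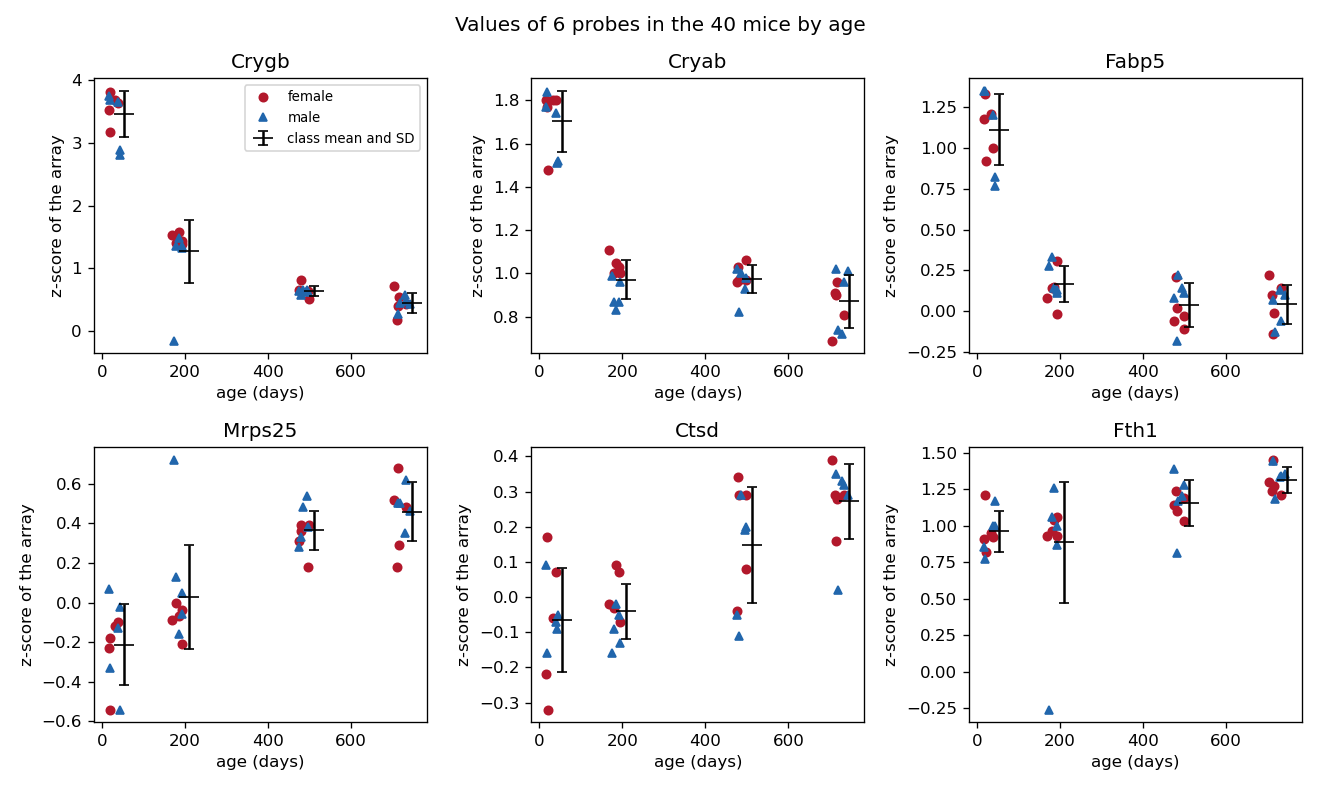
Scores (z, y axis) of Crygb, Cryab, Fabp5, Mrps25, Ctsd and Fth1 against age in days (x axis), 1 point per mouse (triangles males, circles females), with the mean and SD of each age class of 10 mice. Crygb, Cryab and Fabp5 were highest in the youngest class (means 3.46, 1.70 and 1.11), and Mrps25, Ctsd and Fth1 were highest in the oldest (means 0.458, 0.272 and 1.31).

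In all, 461 of 16896 probes passed for the age slope, 284 higher and 177 lower with age, and they named 273 genes. The other largest named rises were Tpm2, a tropomyosin of muscle (0.244 z per year, adjusted p = 0.0298; its second probe gave -0.0114), Numa1, a protein of the mitotic spindle poles (0.228, adjusted p = 0.00724; other probes 0.0419 and -0.0312), E330034G19Rik (0.214, adjusted p = 0.0298; other probes 0.0615 and 0.00882) and Med10, a Mediator subunit (0.203, adjusted p = 0.000187; other probe 0.106). The other largest named falls were Mdh1, the cytosolic malate dehydrogenase (-0.832), the DNA glycosylase Neil3 (-0.688), the Golgi protein Acbd3 (-0.650), the neuronal ubiquitin hydrolase Uchl1 (-0.631) and Akna (-0.617, adjusted p = 0.0374). On the inferred layout Mdh1, Neil3, Acbd3 and Uchl1 lay in the print series of Crygb, and the other probes of Mdh1 (median 0.0657), Acbd3 (0.0388) and Uchl1 (0.0133) had slopes above 0. Med10 lay 1 grid step from Lyz2, which also rose. Numa1 lay in print series 13 of design B, in the same grid line as the Ctsd probes. Of the genes described below, P4ha1 and Tpm1 lay in series 8 of that design and Cct2 in series 6. Of the 284 rises, series 6, 8, 11 and 13 of design B held 48, 66, 24 and 32, so rises within such a series are not independent.

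Among the lists, both measured crystallins fell, over all probes and adjusted over the list alone. Of 34 collagen and matrix genes, 28 had slopes below 0, with 1 fall and 1 rise past the threshold and 4 falls and 1 rise adjusted over the list alone (camera, down, adjusted p = 0.0597). Sparc, a secreted matrix glycoprotein, fell on 1 probe (-0.159 z per year, adjusted p = 0.00402), while its other 3 probes gave -0.225 (adjusted p = 0.0556), 0.0512 and 0.0284. P4ha1, a subunit of the collagen-modifying prolyl 4-hydroxylase, rose by 0.130 (adjusted p = 0.0109), and Col4a1 gave -0.0793 (adjusted p = 0.0619). Col1a2, a chain of type I collagen, fell by 0.437 (adjusted p = 8.43e-05) on 1 probe and gave -0.0629 on the brighter one that stood for it in the list.

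Of 10 microglia, macrophage and complement genes, 2 rose over all probes and adjusted over the list alone: the lysozyme gene Lyz2 (0.201 ± 0.0272 z per year, SE, adjusted p = 1.07e-05) and Ctsd, while Ctsz gave -0.102 (adjusted p = 0.201) and the list did not pass (adjusted p = 0.636). Of 35 heat shock and chaperone genes, 1 rose and 2 fell (2 and 2 adjusted over the list alone): Hspb1, a small heat shock protein, fell by 0.351 (SE 0.0474, adjusted p = 1.07e-05), Hspa8, the constitutive heat shock chaperone, fell by 0.0942 (adjusted p = 0.0218; its other 3 probes had a median of 0.0378 and the mean of all its probes a slope of 0.0144), and the chaperonin subunit Cct2 rose by 0.131 (adjusted p = 0.0157; other probe 0.0423). Hsp90aa1 rose on 2 probes outside the list's choice (0.144 and 0.156, adjusted p = 0.0306 and 0.0386), and of its other probes 1 had a slope below 0 (-0.0229). The list's median was 0.0117, its mean -2.34e-06 and its test pointed down (adjusted p = 0.949).

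Of 61 respiratory chain and ATP synthase genes, Uqcrc2 of complex III rose (0.111, adjusted p = 0.0148; other probe 0.128) as the 1 call over all probes and the 1 adjusted over the list alone, and Sdhd (0.127, adjusted p = 0.0545) and Ndufb11 (0.151, adjusted p = 0.0778) did not pass. Of 32 antioxidant genes, Gpx3, the secreted glutathione peroxidase, rose (0.197 ± 0.0448, SE, adjusted p = 0.00960), also as the 1 call adjusted over the list alone. Gstm1 gave -0.0938, Hmox1 -0.0877 and Prdx3 0.0852. The antioxidant list had a median of -0.0120, a mean of 0.000602 and a test pointing down (adjusted p = 0.949). Of 6 skeletal muscle genes, which stand for the muscles attached to the eyeball, Tpm1 rose (0.187, adjusted p = 0.0115; other probes 0.188 and 0.0857), and 2 rose adjusted over the list alone, with Actn3 at 0.112 and Mylpf at 0.0908 (list adjusted p = 0.0741). None of 9 pigment epithelium genes passed over all probes and 1, Stra6, the retinol transporter (-0.0625, adjusted p = 0.0585 over all probes), was lower adjusted over the list alone.

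Limma's camera passed 0 of 21 lists for the age slope, with 2 at an unadjusted p under 0.05; the collagen and matrix list, the lowest, passed with an estimated correlation (adjusted p = 0.0384) and with the set as a block (adjusted p = 0.0458). Count and direction depended on the fit: 1014 probes passed with the set as a block, 740 without the design A array of mouse 59, 116 in sets 1 to 3 and 99 in sets 4 and 5, and after local centring 287 passed, 96 higher and 191 lower, of which 117 were among the 461, 116 with the same sign (137 higher and 222 lower after print-series centring). After local centring Mrps25, Tpm2, Fth1, Ctsd (1 probe), Uqcrc2, Gpx3, Crygb, Cryab, Col1a2, Sparc, Hspb1 and Fabp5 passed, and Numa1, E330034G19Rik, Med10, Akna, P4ha1, Lyz2, Tpm1, Cct2, Hspa8 and Hsp90aa1 did not (adjusted p between 0.0527 for Numa1 and 0.890 for Cct2). Of the 461 slopes 435 kept their sign after local centring. The median size of all 461 went from 0.135 (median SE 0.0330) to 0.0695 (0.0262). That of the 345 that were not called with the same sign, which were picked by that outcome, went from 0.131 (0.0319) to 0.0497 (0.0245). Akna gave -0.488.

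Other settings, 20 or 21 per gene besides left-out mice, also ended slope calls. Those that did so with the sign kept were 0 for Crygb, 1 for Mrps25, Cryab, Mdh1, Neil3, Uchl1 and the stronger Ctsd probe, 2 for Fabp5, Col1a2, Hspb1 and Acbd3, 4 for Sparc, Med10 and Lyz2, 5 for Gpx3, and 6 for Fth1 and Uqcrc2. They were 7 for Tpm2, Numa1 and the other Ctsd probe, 8 for Tpm1, 10 for P4ha1, Cct2 and Hspa8, 11 for Akna, 12 for E330034G19Rik and 13 for Hsp90aa1. Fth1 did not pass with log2 of age (adjusted p = 0.0794), in sets 1 to 3 (0.0697), without the mice of 17 to 21 days (0.0985) or in an F test over classes (0.0986). Uqcrc2 and Tpm2 did not pass with the array median as a covariate (0.209 and 0.437). Hsp90aa1 did not pass with quantile normalization (0.0602). Without the 10 youngest mice 5 probes passed, with Crygb at -0.562. The slopes of Cryab (-0.0630, adjusted p = 0.470), Fabp5 (-0.0875, adjusted p = 0.416), Col1a2 (-0.0815), Uchl1 (-0.0697), Acbd3 (-0.130), Neil3 (-0.139), Mdh1 (-0.204), Hspb1 (-0.213) and Sparc (-0.0205) were then nearer to 0 and did not pass. Those of Fth1 (0.295) and Gpx3 (0.239) were farther from 0 and did not pass either (adjusted p = 0.225 for both). The Fth1 slope includes the -0.26 of mouse 59, from the last part of its design A array. The other mice of 169 to 194 days scored 0.87 to 1.26. This array makes the slope steeper, and without it Fth1 need not be farther from 0. Mice were numbered from young to old within each set, so that order cannot be told apart from age. A fit with that rank, the set as a block and without the design A array of mouse 59 gave 92 of the 177 falls a slope above 0, 28 of them past the threshold, and 40 of the 284 rises a slope below 0.

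Maturation was addressed by the contrast of the adult class (169 to 194 days) with the youngest (17 to 44 days). Crygb was 2.19 z lower in adults (-2.19, SE 0.139, adjusted p = 3.31e-14), with scores of 2.81 to 3.81 in the 10 young mice and -0.15 to 1.58 in the 10 adults. The -0.15 is from the last part of the design A array of mouse 59, and the other adults scored 1.32 to 1.58. Cryab fell by 0.732 (SE 0.0503, adjusted p = 2.77e-13), from 1.70 ± 0.141 to 0.971 ± 0.0891, and Fabp5 fell by 0.948 (SE 0.0695, adjusted p = 1.34e-12), from 1.11 ± 0.220 to 0.165 ± 0.110. Hspb1 fell by 0.422 (SE 0.0892, adjusted p = 0.00867). In total 65 probes passed, 64 lower and 1 higher in adults, the latter an unnamed probe of design A (0.749 ± 0.178, SE, adjusted p = 0.0379).

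The other largest named falls were Mdh1 (-1.60), Neil3 (-1.39), Uchl1 (-1.38), Acbd3 (-1.27) and Hacd2, an enzyme of fatty acid elongation (-1.25). All of these lay in the print series of Crygb, and of the 51 falls on design A, 49 did, Crygb included. Its 48 companions lay a median of 3.16 grid steps from Crygb, against 8.25 for all probes of the series. Of the 30 genes named by these falls 14 had other probes, 20 in all, which had a median change of -0.0525 and none passed: Uchl1 gave -0.176 on its other probe, Acbd3 0.110 and Mdh1 -0.0650 and -0.147. After local centring Crygb gave -1.29, Mdh1 -0.832, Neil3 -0.628 and Acbd3 -0.620, against -1.36 for Uchl1 and -1.13 for Hacd2. If signal spread from Crygb to its neighbours, local centring would also take part of the fall from Crygb itself. Without this print series 12 probes passed.

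**Figure D3:**
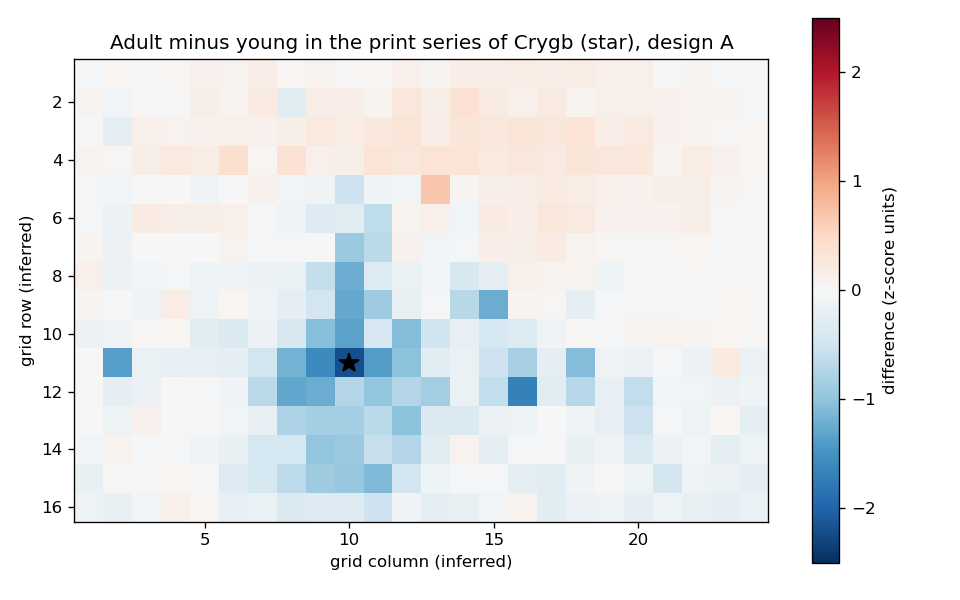
Difference between the adult and the youngest class (z, colour) of each probe in the print series that holds Crygb, at its inferred place in a grid of 16 lines (y axis) and 24 columns (x axis); the star marks Crygb (-2.19). The falling probes lay a median of 3.16 grid steps from Crygb, and the probes of the whole series a median of 8.25.

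Of 34 collagen and matrix genes, 1 fell over all probes and 2 adjusted over the list alone. Sparc fell on 2 of its 4 probes (-0.345 ± 0.0501 and -0.641 ± 0.110, SE, adjusted p = 1.56e-05 and 0.000332), with 0.0560 and -0.0710 on the others. Col1a2 fell by 0.854 (SE 0.0796, adjusted p = 5.57e-10) on 1 probe, while the brighter one gave -0.105 (adjusted p = 0.998); Col4a2 gave -0.275 and Col2a1 -0.158. Camera gave the list an adjusted p of 0.115 (down), 0.0610 with an estimated correlation, 0.0429 without mouse 59 and 0.00853 after local centring. Of 64 cytosolic ribosomal protein genes none passed over all probes or over the list alone, with 40 below 0 (Rps20 -0.453, Rpsa -0.216, Rpl41 -0.173), and the list had an adjusted p of 0.260, or 0.957 with an estimated correlation. Among 15 neuron and synapse genes 1 fell, Uchl1, also adjusted over the list alone (Stx3 0.146, Camk2d 0.117 and Atp1b1 -0.0870 did not pass; list adjusted p = 0.542). Neither of the 2 measured further lens genes passed (Tmem40 -0.143 and Gja1 -0.0370), also adjusted over the list alone.

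Within sets 1 to 3, 54 probes passed for this contrast, and within sets 4 and 5 42 did, with Crygb at -1.89 and -2.26 and Fabp5 at -0.925 and -0.983. After local centring 42 probes passed, and Crygb, Cryab, Fabp5, Col1a2, Hspb1 and both falling Sparc probes were among them. Hspb1 did not pass in sets 1 to 3 (-0.433, adjusted p = 0.131) or in sets 4 and 5 (-0.563, adjusted p = 0.358). In sets 4 and 5 the falling Sparc probes did not pass either (-0.320 and -0.563, adjusted p = 0.817 and 0.142).

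Ageing after maturity was addressed by the oldest class (704 to 743 days) against the adult class, in which 4 probes passed. Crygb fell further, by 0.821 z (SE 0.139, adjusted p = 0.00576), from 1.27 ± 0.506 to 0.449 ± 0.152. The adult mean and SD include the -0.15 of mouse 59, against 1.32 to 1.58 in the other adults. Ctsd rose by 0.313 on 1 probe (SE 0.0590, adjusted p = 0.0286), from -0.0410 ± 0.0788 to 0.272 ± 0.107, with 0.365 (adjusted p = 0.0690) on its other probe, in the same grid line. Mrps25 rose by 0.431 (SE 0.0838, adjusted p = 0.0344), from 0.027 ± 0.262 to 0.458 ± 0.149. An unnamed probe of design B rose by 0.513 (SE 0.0561, adjusted p = 6.38e-07).

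The next genes by p, Fam13b (0.229, adjusted p = 0.211) and Coa3 (-0.216, adjusted p = 0.262), did not pass, nor did Fth1 (0.426) or Cryab (-0.0990). The 0.426 of Fth1 is raised by the design A array of mouse 59, which scored -0.26 against 0.87 to 1.26 in the other adults. Of the 2 crystallins 1 fell, Crygb, also adjusted over the list alone. Of 10 microglia, macrophage and complement genes none passed over all probes and 2 were higher adjusted over the list alone, with Lyz2 at 0.228, Ctsz at -0.191 and Serping1 at -0.142; the list's median was -0.00900, its mean 0.0295 and its test pointed up (adjusted p = 0.757). Gpx3 was the 1 antioxidant gene of 32 that was higher adjusted over the list alone (0.364, adjusted p = 0.262 over all probes), in a list with a median of -0.0120, a mean of 0.0118 and a test pointing down (adjusted p = 0.976). None of 61 respiratory chain genes passed, over all probes or adjusted over the list alone (Cox5b 0.215, Atp5g3 0.145, Atp5o 0.214; list adjusted p = 0.367). All 10 measured circadian clock genes were above 0, among them Tef (0.457, but 0.0417 without the design A array of mouse 59 and -0.0183 in sets 1 to 3), Rora (0.266), Nr1d2 (0.123) and Npas2 (0.149, but -0.0768 in sets 4 and 5), with none past the threshold, over all probes or adjusted over the list alone, and a list adjusted p of 0.366, or 0.04999 after local centring.

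Limma's camera passed 0 of 21 lists here, with 2 at an unadjusted p under 0.05, and limma passed 1711 probes at that level. In a fit of only the 20 mice of both classes, Crygb (adjusted p = 0.137) and Mrps25 (0.216) did not pass, with the differences unchanged at -0.821 and 0.431. After local centring Mrps25 gave 0.329 and Ctsd 0.170 and neither passed (adjusted p = 0.448 and 0.431). The Crygb and Mrps25 probes lie in the last part of the design A array of mouse 59, which the fit of 20 mice kept. Without that array, in the fit of all classes, Crygb gave -0.974 (adjusted p = 2.88e-08), and -0.878 after local centring (adjusted p = 1.46e-11). Mrps25 then passed both before local centring (0.505, adjusted p = 5.67e-05) and after it (0.435, adjusted p = 0.000445), while Ctsd did not pass after it (0.353). Without mouse 27 neither passed (0.0707 for both), and leaving out any of 16 mice ended the call of Mrps25 (adjusted p of 0.0549 to 0.109) and any of 13 that of Ctsd (0.0553 to 0.0890). In sets 1 to 3 and sets 4 and 5 the differences were -1.05 and -0.867 for Crygb, 0.25 and 0.407 for Ctsd and 0.517 and 0.465 for Mrps25.

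Within the youngest class, mice of 33 to 44 days were compared with mice of 17 to 21 days, 5 of each. Both young mice of set 3 were 17 to 21 days old, and both of set 5 were 33 to 44 days old. The contrast is thus partly mixed with differences between sets. With the set as a block 0 probes passed. Crygb differed by -0.227 (SE 0.196), Cryab by -0.0485 and Fabp5 by -0.232 (SE 0.0926), none past the threshold. The genes with the lowest p were Bmp1, a procollagen C-proteinase (0.347), Esyt1 (0.494), Cnep1r1 (0.340), Zfp61 (-1.67) and Gm6083 (-0.724), all with a limma adjusted p of 1.00. Limma passed 0 of 16896 probes, with 606 at an unadjusted p under 0.05. Of 61 respiratory chain genes 40 were higher in the older juveniles (Ndufa8 0.310, Cox7a2l 0.328, Atp5a1 0.206), of 64 ribosomal protein genes 45 (Rpsa 0.248, Rps12 0.220, Rpl4 0.220), and of 57 cell cycle genes 40 (Bub1b 1.01 and Ccna2 0.309, against Kif23 -0.518 and Cenpa -1.23). None of these passed, over all probes or adjusted over the list alone, and camera gave the lists adjusted p of 0.339, 0.437 and 0.472, with 0 of 21 lists passing and 2 at an unadjusted p under 0.05. The 2 crystallins gave 0 calls over all probes and adjusted over the list alone. With array weights 8 probes passed, and without 1 female of the youngest class (replicate 4) 2 did.

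Males and females were compared over all ages, 20 of each. Xist, the RNA that silences an X chromosome in females, scored -0.917 ± 0.388 in males and -0.509 ± 0.284 in females (SD, n = 20 each), a difference of -0.408 (SE 0.102, adjusted p = 0.994). The Y-linked Eif2s3y scored -0.609 ± 0.439 in males and -0.922 ± 0.192 in females (0.313, SE 0.104, adjusted p = 0.994). Of the 8 measured X- and Y-linked genes none passed over all probes, and adjusted over the list alone 1 was higher and 1 lower in males. The others differed by -0.127 for Eif2s3x, -0.0800 for Ddx3x, -0.0670 for Kdm6a, 0.0540 for Zfx, 0.0215 for the Y-linked Uty and 0.00350 for Kdm5c. Klhl23 (0.155), B230308N11Rik (0.201), Tpm1 (0.257) and Golim4 (0.162) were next to Xist in p and did not pass either (adjusted p = 0.994).

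Of 6 skeletal muscle genes 5 were higher in males, none past the threshold over all probes and 3 adjusted over the list alone, with Tpm2 at 0.233, Actn3 at 0.155 and Mylpf at 0.154. Camera passed this list alone of 21 (up, adjusted p = 0.0375), and the adjusted p was 0.845 with an estimated correlation, 0.0519 without mouse 59, 0.0659 with the set as a block and 0.00157 after local centring. Leaving out any of 17 mice also ended this call (adjusted p of 0.0519 to 0.274). None of 10 glial genes passed, over all probes or adjusted over the list alone (Vim 0.111, Glul 0.0880, Car2 0.0630, Stat3 -0.127; list adjusted p = 0.832). Limma passed 0 of 16896 probes for sex, with 813 at an unadjusted p under 0.05. Xist and the Y-linked Eif2s3y, whose RNA differs between the sexes, did not pass and had mean scores below 0 in both sexes. The 0 calls therefore do not show that the sexes were alike.

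Whether the age slope differed between the sexes was tested as an interaction. Limma passed 0 of 16896 probes, with 268 at an unadjusted p under 0.05. Of 64 cytosolic ribosomal protein genes, 50 had a higher slope in males than in females, none of them past the threshold over all probes or adjusted over the list alone, and camera gave the list an adjusted p of 0.0258, or 0.829 with an estimated correlation. In females the median slope of these genes was -0.0106 z per year, with 28 above 0 and 36 below, and in males 0.0216, with 44 above and 20 below. Without mouse 59 the list had an adjusted p of 0.0909 and after local centring 0.118. The 2 crystallins gave 0 calls, over all probes or adjusted over the list alone.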

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

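The tests of the Crygb print series, of the lists in the interaction, of the design A array of mouse 59, of the running-number sets, of the order within them, of regional shifts (on a layout inferred from the values), of the slopes shared by both batches and of the sets in the split with 282 calls were chosen only after the result or the data were seen. The counts over other splits of the mice were set before.

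Of 51 falls between the youngest and the adult class on design A, 49 lay in 1 print series, that of the Crygb probe, itself included. Each of the 48 falls beside it may be lower mRNA of its own gene, or signal that spread on the filter from the Crygb spot. Against lower mRNA, for the 14 of 30 named genes that have other probes, these changed by a median of -0.0525 z, which is 0.0600 of the median change of the falling probes (-0.875), and none of the 20 passed, while the other genes and the unnamed probes have no such test. Signal spreading from Crygb has the values it needs for the 37 falls within 5 grid steps, of which local centring left a median share of 0.354 with 13 still passing (all 48 lay a median of 3.16 steps from Crygb, against 8.25 in the series), but as the whole cause it is argued against for the 11 farther falls as a set, of which it left 0.847 with 9 passing (Uchl1 went from -1.38 to -1.36 and Hacd2 from -1.25 to -1.13). What lowered these 11 stays open. Against lower mRNA of each gene, 49 of the 51 falls on design A lay in this print series, with 1 each in series 6 and 21. The 5 other probes of the genes named by the 11 changed by a median of -0.054 z, and 0 passed. This argues against it for the 11 as a set, unless genes that fall were printed together, and does not test single genes. The layout was inferred from the same data. Crygb has no other probe, so its own fall rests on 1 spot. That fall was 0.978 z per year after local centring, which also subtracts any signal that spread from Crygb to its neighbours.

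The 461 calls for the age slope were weighed against shifts of signal in regions of the filters, differences between sets and the order of the mice. Only 25.2% of these probes passed with the same sign after local centring. Over all 461 the median slope size went from 0.135 z per year (median SE 0.0330) to 0.0695 (0.0262). The median share left was 0.495, and regional shifts would give such smaller slopes. The 345 that no longer passed with the same sign went from 0.131 (0.0319) to 0.0497 (0.0245). They were picked by that outcome, so their own shrinkage decides nothing. Of the 461, 435 kept their sign, and single slopes moved less (Akna -0.617 to -0.488, Rpl31 -0.160 to -0.139). With the set as a block 100% passed with the same sign, an outcome given by the design because every set holds 1 mouse of each group. By the same balance, differences common to all mice of a set hardly enter the slopes (r = 0.999952 between slopes with and without the block). This argues against such differences as the source of the calls. Set differences that vary with age were not tested. With the rank within the set as a covariate, the set as a block and without the design A array of mouse 59, all in 1 fit, 0% passed with the same sign (92 of the 177 falls turned to slopes above 0, 28 of them past the threshold), and since rank followed age with r = 0.967, order and age cannot be told apart by it. Slopes fitted in sets 1 to 3 and in sets 4 and 5 correlated across probes with r = 0.228, and of 100 reassignments of ages within sets and sexes, the real one included, 2 gave as much (highest other 0.231), so a change with age or with order common to both groups of sets stays open beside regional shifts, as does ageing itself, which was not tested apart from order.

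The median correlation of the design A array of mouse 59 (male, 169 to 194 days) with the others was 0.426, far from the 0.934 of the other mice of its group. A different state of this eye is argued against by the design B array of the same mouse, whose mean correlation with the others was 0.907, within their 0.889 to 0.950. Values set at wrong probes in the last part of the table remain a candidate explanation: in 13 of 22 print series that part matched another position with r above 0.7 (highest 0.941). Each of these 13 matched a different print series at a shift of 0 places, as series 8 did with series 12 (r = 0.941, against 0.0367 at its own place). The remaining series had no match above 0.7. The Crygb probe, which scored -0.15 here against a median of 1.355 in the group's other mice, lies in that last part, while a Sparc probe with 1.01 against 0.645 lies before it and is not covered by this explanation.

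Among 112 groups of 5 mice examined for a mouse far from the rest, 10 showed one, where chance gives 1 in 20, or 5.6. On design B, mouse 23 (male, 476 to 499 days) had a median correlation of 0.903, against 0.943 for its group. Cryab scored 1.48 in 1 young female (mouse 30), against a median of 1.80 in the other young females. Ctsd scored 0.02 in 1 male of the oldest class (mouse 40), against 0.325. In 1 male of 476 to 499 days (mouse 37), 2 Sparc probes scored -0.25 against 0.365 and 0.38 against 0.81. Xist scored -0.13 in 1 female of 476 to 499 days (mouse 52), against -0.655, and 0.34 in 1 female of the oldest class (mouse 67), against -0.64. The age slope of the ribosomal protein list differed between the sexes (camera adjusted p = 0.0258 for the interaction, with 50 of 64 genes higher in males), a call lost with an estimated correlation (adjusted p = 0.829), without mouse 59 (0.0909) and after local centring (0.118).

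Other splits of the mice were drawn, 100 for each result with the real one included. For the age slope 1 split, the real one, gave as many probes (461, highest other 4), and for adult against young 1 did (65, highest other 5), so chance can be excluded for both counts. For old against adult 2 splits gave as many as the real 4 (highest other 5), a share under the 0.05 set before. Another split gave more probes than the real one, and leaving out any of 11 mice cut the real count to 2. Chance is therefore not firmly excluded for this count, and the splits do not test single probes. Leaving out 1 mouse ended the calls of Mrps25 (16 mice) and Ctsd (13 mice) but in no case that of Crygb. Crygb did not pass in the fit of only the 20 mice of both classes (limma adjusted p = 0.137). The unnamed probe of design B had a limma adjusted p of 6.38e-07. The real count was 0 for the youngest class, sex and the interaction, and for the lists in the age slope, old against adult and the youngest class. Any split reaches 0 (100 of 100 each), so the splits decide nothing there (highest others 282, 4 and 1 for probes, and 2, 3 and 4 for lists). The 282 came from 1 split of the youngest class, which points to a structure among these 10 mice: it set sets 1 and 5 against sets 3 and 4, with set 2 on both sides. It gave 324 with the set as a block, and the other splits that kept as many sets whole, 25 with this one, gave at most 8. The block is shared by all ages of a set, and most of those splits group other sets together. Neither can therefore exclude differences between these sets among the youngest mice, and the source of the 282 stays open. For the lists in the sex difference, 36 splits gave as many as the real 1 (highest other 4), so chance cannot be excluded there.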

How the results depend on the processing

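Fits without mouse 59 or its design A array, on parts of the sets, with local or print-series centring, without the Crygb print series and with the rank within the set (together with the set as a block and without that array) were chosen after seeing the data; all others were planned, and planned z-scores per array were not run because they repeat the deposited scale. Signal over background is unknown, so which probes were too dim to measure cannot be told. Except where the construction gives it (fewer mice, fewer probes, a covariate that follows age), the cause of a change below was not tested. Scale, base and filter places are limits on every value.

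For the age slope (461) the count was 1014 with the running-number set as a replicate block, which takes set differences out of the spread and moved the slopes very little (r = 0.999952 between slopes with and without it), 740 without the design A array of mouse 59, 1309 with both, 189 with the array median as a covariate, 208 with the mean of a gene's probes, 116 in sets 1 to 3, 99 in sets 4 and 5, 287 after local centring, 36 with the rank within the set, the block and without that array, 52 without the mice of 17 to 21 days, 5 without the youngest class and 109 with an F test over classes. Leaving out each mouse gave 266 to 669, with 266 without female 17-44d replicate 1 and 288 without male 17-44d replicate 3. Leaving out 1 mouse ended slope calls of Akna (male 17-44d replicates 1, 3 and 5, female 17-44d replicate 1, male 704-743d replicates 4 and 5 and female 704-743d replicates 4 and 5; adjusted p 0.0537 to 0.0852), Tpm2 (female 17-44d replicate 1, male 17-44d replicate 3 and female 704-743d replicate 2; 0.0518 to 0.0620), E330034G19Rik (male 17-44d replicate 1, female 17-44d replicates 1 and 2 and male 704-743d replicate 5; 0.0514 to 0.0558) and Hsp90aa1 (male 704-743d replicate 5; 0.0687). The block changed no other count of probes by over 1.5 times, and it pairs mice of a set by running number only.

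Old against adult (4) gave 14 with array weights, 2 without mouse 27, 7 in sets 4 and 5 and 2 to 5 when each mouse was left out, with 2 without male 704-743d replicates 1, 2 and 5, male 169-194d replicates 2, 3 and 4, female 169-194d replicates 3, 4 and 5 and female 704-743d replicates 4 and 5. The call of Mrps25 ended without any of 16 mice (all of both classes but female 704-743d replicates 1 and 3, male 704-743d replicate 4 and male 169-194d replicate 5; adjusted p 0.0549 to 0.109) and that of Ctsd without any of 13 (all but male 169-194d replicate 1, female 169-194d replicates 1 and 2, male 704-743d replicate 3 and female 704-743d replicates 1, 2 and 3; 0.0553 to 0.0890). Crygb (0.137) and Mrps25 (0.216) did not pass in a fit of only the 20 mice of both classes, with unchanged differences. Over 18 other settings the adjusted p of Mrps25 and Ctsd ran from 1.78e-06 to 0.448 and from 0.00144 to 0.999. Adult against young (65) gave 38 with the mean of a gene's probes, 42 in sets 4 and 5, 42 after local centring and 12 without the Crygb print series. In this contrast Crygb passed in the same direction in all 16 other settings that kept its probe (highest adjusted p 1.49e-08), as did Cryab (17 settings, 0.000134), Fabp5 (17, 0.000103) and Col1a2 (17, 0.00503), and no left-out mouse ended these calls. The youngest class (0) gave 8 with array weights and 0 to 2 when each mouse was left out (2 without female 17-44d replicate 4). Sets 4 and 5 hold a single mouse of 17 to 21 days, so their count is not given. Sex and the interaction gave 0 with limma in every setting run, against 813 and 268 at an unadjusted p under 0.05.

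For lists, the age slope (0) gave 1 with the block, 1 with an estimated correlation, 1 after local centring and 0 to 2 when each mouse was left out: 2 without male 169-194d replicate 1, female 704-743d replicate 3, female 17-44d replicate 5 or male 704-743d replicate 5, and 1 without male 169-194d replicates 3 or 4, female 169-194d replicates 4 or 5, male 704-743d replicate 4 or female 704-743d replicate 5. Old against adult (0) gave 1 after local centring. The youngest class (0) gave 0 to 2, with 2 without female 17-44d replicates 2 or 4. Sex (1) gave 0 with the block, with the array median as a covariate, with an estimated correlation, without mouse 59 and with the block and without mouse 59, and 0 to 1 when each mouse was left out. It was 0 without male 169-194d replicates 1 and 5, female 169-194d replicates 1 and 2, male 704-743d replicates 1 and 4, female 704-743d replicates 1 and 3, male 17-44d replicates 2, 4 and 5, female 17-44d replicates 3 and 4, male 476-499d replicates 4 and 5 and female 476-499d replicates 2 and 4, with adjusted p of 0.0519 to 0.274 for the muscle list.

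Single genes changed sign as follows. With the mean of a gene's probes: slopes of Hspa8 0.0144 and of Sparc A2977 and A4342 -0.0760, adult against young Sparc A2977 -0.250, and in the youngest class Ccna2 -0.218 and Sparc A6518 0.000833. In sets 1 to 3: Tef (old against adult) -0.0183, Gja1 0.0400, Sparc A4342 0.00500 and Mdh1 A6481 0.0550 (adult against young) and Sparc B14923 -0.0564 (youngest). In sets 4 and 5: the slope of Sparc A4342 -0.0625, Npas2 -0.0768 (old against adult), Sparc A2977 -0.0298 (adult against young), Ndufa8 -0.0727 and Sparc A4342 -0.116 (youngest, with a single mouse of 17 to 21 days). After local centring: slopes of Rdh11 -0.0131, Sparc A4342 -0.0213 and Rpl10 -0.00968 and -0.0173, Atp1b1 0.00540 (adult against young), and for sex Zfx -0.00596 and Kdm5c -0.0200. With local centring and without the design A array of mouse 59: Rdh11 -0.00918, Sparc A4342 -0.0381, Rpl10 -0.00968 and -0.0173, Tef -0.00914, Atp1b1 0.0216, Sparc A2977 -0.000698 (adult against young), Zfx -0.00596 and Kdm5c -0.0200. With array weights: Gja1 0.0173, Sparc A2977 -0.00849 (adult against young) and Kdm5c -0.0124. Elsewhere: Sparc A2977 -0.00101 with the block (youngest), Kdm5c -0.00175 with print-series centring and the slope of Sparc A6518 0.0466 without the youngest class.

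With the rank within the set as a covariate, which follows age, together with the set as a block and without the design A array of mouse 59, slopes turned for Tpm2 (-0.174), Med10 (-0.116), Lyz2 (-0.130), Tpm1 (-0.183), Crygb (3.60), Mdh1 (3.31), Neil3 (2.92), Acbd3 (3.09), Uchl1 (2.99), Cryab (1.84), Col1a2 (1.82), Sparc B14923 (0.894) and A6518 (1.05), Col4a1 (0.0278), Hspb1 (0.971), Hmox1 (0.199), Stra6 (0.0537), Fabp5 (2.13), Rpl41 (0.308) and Mcm4 (0.00958). Leaving out each mouse turned signs within -0.0593 to 0.0199 for Gja1 (adult against young; without female 169-194d replicate 4), -0.0502 to 0.818 for Rpl26 (youngest; without male 17-44d replicate 3), -0.00961 to 0.127 for Sparc A4342 (youngest; without female 17-44d replicate 3), -0.0188 to 0.0522 for Uty (3 mice, lowest without female 169-194d replicate 4) and -0.00674 to 0.0114 for Kdm5c (12 mice, lowest without male 476-499d replicate 2). Outside that fit with the rank, Hspa8 and Rpl10 were the genes with a called value that changed sign.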

Other observations

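The tests of the matrix genes after the first weeks and of the spots around Cryab, Col1a2, Lyz2 and an unnamed probe were chosen only after the result was seen; those of the lysosomal genes and of ferritin were set before, except for the local centring of the ferritin probes and the lysosomal list without Ctsz and Laptm5. Genes named in this part were chosen after their values were seen.

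Further gene lists did not pass as lists for the age slope, though single members did. Of 6 antigen presentation genes, the peptide transporter subunit Tap2 rose (0.158 ± 0.0424 z per year, SE, adjusted p = 0.0321, and 0.639 after local centring) and the class I heavy chain H2-K1 fell by 0.120 (SE 0.0296, adjusted p = 0.0177, and 0.0463 after local centring), with 2 rises and 1 fall adjusted over the list alone (list adjusted p = 0.723). Of 10 interferon response genes 9 had slopes above 0, with 0 calls by limma over all probes or adjusted over the list alone (list adjusted p = 0.355). Of 64 ribosomal protein genes Rpl10 rose (0.144 ± 0.0330, adjusted p = 0.00980, and 0.682 after local centring) and Rpl31 (-0.160 ± 0.0433, adjusted p = 0.0338, and 0.0783 after local centring) and Rpl41 (-0.120 ± 0.0336, adjusted p = 0.0409, and 0.126 after local centring) fell, with 3 rises and 2 falls adjusted over the list alone (list adjusted p = 0.949). The 3 other probes of Rpl10 had slopes of 0.0994, 0.0953 and 0.0762, the first pair also past the threshold but at -0.00968 and -0.0173 after local centring. On the inferred layout all called Rpl10 probes lay in the same grid line of print series 8 of design B. That series held 66 rises and 1 fall, so these probes are not independent. Tap2 lay in print series 6 of design B, which held 48 rises and 0 falls. Rpl31 also fell on a second probe (-0.156) and gave -0.0181 on the remaining one, and Rpl41 fell on another probe (-0.152) and gave -0.112 and -0.0666 on the rest. Both falling Rpl31 probes lay close together in the same grid line on the inferred layout, so they are not independent. Of 57 cell cycle genes the replication helicase subunit Mcm4 fell by 0.0804 (SE 0.0221, adjusted p = 0.0379, and 0.0890 after local centring), also as the 1 fall adjusted over the list alone, and of 30 proteasome genes 0 passed over all probes and 3 rises and 2 falls did adjusted over the list alone (list adjusted p = 0.949 and 0.885). Leaving out 1 mouse ended the call of Tap2 for 6 of the 40 mice (adjusted p of 0.0502 to 0.0706), of Mcm4 for 11 (0.0523 to 0.0755), of the first Rpl41 probe for 17 (0.0502 to 0.0847) and of the first Rpl31 probe for 7 (0.0519 to 0.0724). It ended that of the Rpl10 probe with a slope of 0.0953 for 23 mice (0.0502 to 0.0787) and that of the second Rpl31 probe for 3 (0.0569 to 0.0627).

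Markers of tissue that a dissected eye could hold gave camera adjusted p for the age slope of 0.636 for 7 red cell genes, 0.723 for 7 adipose and gland genes and 0.0741 for the muscle list. Among the lists with a neural or surface origin it was 0.959 for 10 glial genes, 0.949 for 11 corneal and surface epithelium genes, 0.593 for 15 progenitor genes, 0.723 for 6 melanosome genes and 0.885 for 15 neuron and synapse genes. In adult against young these lists had adjusted p between 0.541 for the red cell genes and 0.912 for the melanosome and adipose genes.

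Since Ctsd rose, lysosomal genes as a whole may have risen with age, a hypothesis tested over the 40 mice with 47 measured genes that left out Ctsd but held Ctsz and Laptm5 of the microglia list. The list's camera p was 0.272 (0.310 with an estimated correlation, and 0.203 over 45 genes without this pair), with 28 genes above 0 and 2 past the threshold, so a rise of the list was not borne out. Since Fth1 rose, the other ferritin subunit may have risen too: 4 of 5 Ftl1 probes had slopes above 0 at an unadjusted p under 0.05 (0.0906 to 0.155 z per year, adjusted p of 0.0622 to 0.302, none passing) and 1 gave -0.0539. Of the 4, 3 lay in columns 18, 20 and 22 of 1 grid line of print series 6, the series of design A with the most higher calls (14), so they are not independent. After local centring 1 of the 5 probes had a slope above 0 at an unadjusted p under 0.05 (0.0826) and those 3 gave 0.0400, 0.0161 and 0.0351, so whether the second subunit rose stays open. All 5 Ftl1 probes also lie in the last part of the design A array of mouse 59, and their slopes without it are not given.

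Matrix genes may have fallen after the first weeks of life: after local centring limma's camera gave the collagen and matrix list p = 0.000406 (down, n = 10 mice per class), or an adjusted p of 0.00853, against an adjusted p of 0.115 before it. This is a hypothesis from the same data, in which 2 of 4 Sparc probes and 1 probe of Col1a2 fell and their other probes did not pass.

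Smaller groups of calls also lay around single bright or changing spots. Around Cryab, 5 further falls between the youngest and the adult class lay a median of 2.24 grid steps away, against 7.81 in the series, and around Col1a2 4 lay 1.5 away, against 9.06. Around Lyz2, 12 rises with age lay 4.62 steps away, against 8.06, and around the unnamed probe of design B with the lowest adjusted p (0.349 ± 0.0301 z per year, adjusted p = 3.86e-10) 47 lay 5.00 away, against 12.04. Other probes of the genes named by the latter, 14 in all, had a median slope of 0.0292, against 0.137 for the called ones, and 0 passed by limma's adjusted p. The print series with the most rises was series 8 of design B, with 66 rises and 1 fall, and 59 of the rises lay in grid lines 10 to 16. It was not examined around a single spot.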
